A study of Homo sapiens with 6 samples.

How the data were processed

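Gene expression was measured in KHOS and U-2OS cells, both established human osteosarcoma lines. Each line had 1 Affymetrix U133 Plus 2.0 array for each of 3 conditions, control, miR-null vector and miR-1 vector, so 6 arrays were analysed. Per the labels' protocols, the vectors were transfected for 48 hours with Lipofectamine LTX and Plus Reagent, RNA was extracted with TRIzol, and each array held a pool of RNA from 3 flasks. Pooling removes the spread between flasks from the values, so the only replication within a treatment was between the lines. The labels name no vector for the control arrays. Whether those cells received the transfection reagent is not given in the sources used here.

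The authors made log2 expression values from the scanned arrays with RMA in Qlucore, per the design text deposited with the series, and the submitters' processing notes also name RMA. The deposited log2 values ran from 2.83 to 14.90, with 0 missing. The design text also describes a scaling to each gene's average over the arrays, but the deposited values were not centred per gene. Array medians lay between 4.98 and 5.15, while interquartile ranges ran from 2.75 to 3.36. The values were used as deposited, with a further quantile normalization as an alternative. RMA shrinks small differences near the floor of the scale, and pooled RNA gives no estimate of spread between cultures. For arrays of this kind the number of arrays limits the precision.

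The table held 54675 probe sets, of which 62 were control probe sets and were left out of the tests. A probe annotation table gave 41091 probe sets 1 gene symbol, 1801 several and 11721 none, and no gene was named from a probe set with several symbols. Of the probe sets with 1 symbol, 41037 matched a RefSeq gene table by Entrez identifier, with 0 symbols updated. Each of 19775 genes was represented by the probe set with the highest mean over all 6 arrays. The 12958 genes whose mean reached the median of all probe sets, a log2 value of 5.11, were tested. A probe set reports the transcripts that carry its target sequence, so related genes can share signal, above all for identifiers ending in x_at.

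Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and a Benjamini-Hochberg adjusted p below 0.05 counted as passing. Treatment and cell line were additive terms over all 6 arrays, which left 2 residual degrees of freedom. This fit gave these contrasts: miR-1 minus miR-null, miR-null minus control, and KHOS minus U-2OS. The line difference in the miR-1 change was an interaction term, with the miR-null and control arrays of a line as its arrays without miR-1. Another pair of contrasts was chosen after seeing the data, because no gene passed between miR-1 and miR-null. They set the miR-null and miR-1 arrays together against control, in both lines jointly and as a line difference. In that line difference the spread came from the miR-null and miR-1 arrays within a line, and each line had 1 control array. P-values here measure the spread between pooled arrays, not between cultures. In the additive fits that spread also holds any difference between the lines in their response to a treatment, so it is not array error alone. In the line difference in the miR-1 change it holds the change from control to miR-null.

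The miR-1 targets and 30 other gene lists were written from general knowledge before the data were examined, as were the tests, the alternatives in the planned set and the rule for naming genes. The other lists were the pentose phosphate pathway, actin cytoskeleton, muscle differentiation, osteoblast, collagen and extracellular matrix, cell cycle G2/M, DNA replication and G1/S, G1 regulators, p53 targets, apoptosis regulators, interferon response, NF-kB and cytokines, immediate early genes, unfolded protein response, heat shock, cholesterol synthesis, hypoxia and glycolysis, EMT and invasion, microRNA machinery, drug transporters, HOX genes, cancer-testis antigens, TGF-beta signalling, growth factor receptors, telomere maintenance, oxidative phosphorylation, epithelial cells, blood cells, endothelial cells, and adipocytes and chondrocytes. Lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over the 31 lists, beside camera with an estimated correlation and fry. With an estimated correlation, camera takes its p from the 2 or 3 residual degrees of freedom of the fit. A list can therefore hardly pass after adjustment, whatever its correlation, and a call lost there does not show that its genes vary together. Camera compares a list with all other genes, so its direction can differ from the sign of a median near that of all genes. A list's median within 1 line was also placed among 10000 random lists matched on mean expression in 20 bins.

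For each main comparison the named genes were the 10 with the largest rise and the 10 with the largest fall among those that passed. Where fewer passed, genes that moved by at least 1.2-fold in the same direction in both lines filled the places, ranked by their smaller change. Up to 4 members of each list with the largest changes, all measured miR-1 targets and the host gene of a miR-1 precursor were named as well.

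The procedure was tested on simulated data, with 200 genes changed by known folds in each of 10 rounds on 12958 genes. For miR-1 minus miR-null it recovered 4.18% of genes changed 2-fold and 86.1% of genes changed 4-fold. For miR-null minus control these shares were 3.28% and 85.5%, and for KHOS minus U-2OS 33.3% and 96.2%. For the vector arrays together against control they were 57.3% and 98.0%, and for the line difference in that change 2.99% and 84.7%. For the line difference in the miR-1 change 0% of the 4-fold genes were recovered. A list of 30 genes shifted by 0.5 on the log2 scale was found in 10 of 10 rounds, and an unshifted list in 0. The simulated genes varied independently of each other. These rounds therefore do not test the preset correlation for lists whose genes vary together.

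Alternatives were all probe sets, no level filter, a 75th percentile level filter, a repeated quantile normalization, centring on array medians, a prior variance that follows the mean, fits without the line or treatment term, fits on the arrays compared alone, other control arrays, an exact Mann-Whitney test and leaving out each array in turn. A result that had not passed was not counted as reversed when its sign changed. A comparison of genes by miR-1 seed sites was not run because 3′ UTR sequences were not used here. No comparison used a genome build, so no coordinates are given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.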

Results

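KHOS and U-2OS osteosarcoma cells were measured on 6 arrays under 3 conditions each, control, an empty miR-null vector and a vector for miR-1, a microRNA of heart and skeletal muscle. KHOS is a line transformed with the Kirsten sarcoma virus, and U-2OS is a line from another osteosarcoma. Array medians ran from 4.98 to 5.02 (log2) in KHOS, lowest with miR-1, and were 5.07, 5.13 and 5.15 for the U-2OS control, miR-null and miR-1 arrays. Arrays of the same line correlated at 0.978 to 0.996 across probe sets and arrays of different lines at 0.910 to 0.937. The first principal component held 87.4% of the variance and the second 6.72%. Each line and treatment had 1 array, so values within a line have no replicate.

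The miR-1 vector was compared with the empty miR-null vector to find transcripts that respond to the microRNA. Changes were small, and none of the 12958 genes passed. The largest increases shared by both lines were in GPX3, an extracellular glutathione peroxidase (0.82 in KHOS and 0.70 in U-2OS, fitted log2 change 0.76 ± 0.17, SE), and EGR3, an immediate early transcription factor (1.24 and 0.68). Shared decreases were led by TRIM22, an interferon-induced antiviral protein (-0.88 and -1.10), and TIE1, an endothelial receptor kinase (-1.04 and -0.77, fitted -0.91 ± 0.20, SE). Known miR-1 targets as a group had a median change of -0.06, against -0.04 for all genes.

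Other genes higher with miR-1 in both lines by values that did not pass were OSR2, a developmental zinc finger factor (0.75 and 0.65), PTX3, a secreted pentraxin of innate immunity (0.63 and 0.63), and PTGER4, a prostaglandin E2 receptor (0.57 and 0.73). C16orf46, OVOL3, WDR35, RAB30 and ZNF276 completed the named increases, with fitted changes of 0.72, 0.77, 0.62, 0.57 and 0.61. On the other side were MX2, an interferon-induced GTPase (-1.02 and -0.63), CDK14, a cyclin-dependent kinase (-0.61 and -0.90), and PDIA3, a protein disulfide isomerase of the endoplasmic reticulum (-0.83 and -0.59). LINC02806, MANSC1, SNCG, SAMD9 and GBP3 had fitted changes of -0.72, -0.62, -0.59, -0.65 and -0.55. The smallest adjusted p in limma was 0.9999, 78 genes had an unadjusted p under 0.05 where 647.9 are expected by chance, and the exact Mann-Whitney test called 0, since 2 arrays against 4 cannot go below p = 0.133. The typical 95% interval reached 0.47 to either side of a fitted log2 change. The spread behind these values also holds differences between the lines in their response to a vector.

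Of 50 known miR-1 targets 42 were measured, 0 of them passed over all genes and 0 passed when adjusted over the list alone. Fitted changes were negative for 27 and positive for 15, and 16 were negative in both lines against 7 positive in both. The most negative were PAX3, a muscle precursor transcription factor (-0.30 ± 0.18, SE), TKT, the transketolase of the pentose phosphate pathway (-0.24 ± 0.22), ATP6V1A, a vacuolar ATPase subunit (-0.23 ± 0.19), and SOX9, a cartilage transcription factor (-0.21 ± 0.30). Targets often used to read out miR-1 lay near 0, with TWF1, an actin-binding protein, at -0.07 ± 0.17, HDAC4, a histone deacetylase, at 0.02 ± 0.17, TAGLN2, a transgelin, at 0.11 ± 0.17, and MET, the hepatocyte growth factor receptor, at -0.16 ± 0.20. NOTCH3, a Notch receptor, had 0.50 ± 0.20 and EDN1, the endothelin precursor, 0.43 ± 0.18. The list's median was -0.06, its mean -0.02 and its direction in camera up, with p = 0.514 at the preset correlation, 0.831 with an estimated correlation and 0.869 in fry. The median was -0.16 without the KHOS miR-1 array, 0.05 without the U-2OS miR-1 array, -0.02 without the KHOS miR-null array and -0.09 without the U-2OS miR-null array. In KHOS its median of -0.02 lay at percentile 68.0 of matched random lists and in U-2OS its median of -0.10 at percentile 8.75. MIR1-1HG, the host gene of a miR-1 precursor, differed by 0.11 in KHOS and 0.36 in U-2OS, but its probe set does not read the mature microRNA or a vector transcript.

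Across genes, which are not independent replicates, the miR-1 change in KHOS and that in U-2OS had a Pearson r of -0.062 and a Spearman rho of -0.087. By at least 1.2-fold, the fold named in the design text, 117 genes were higher and 285 lower in both lines, 402 together against 407.4 expected for independent lines, and 443 moved in opposite directions.

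**Figure D1:**
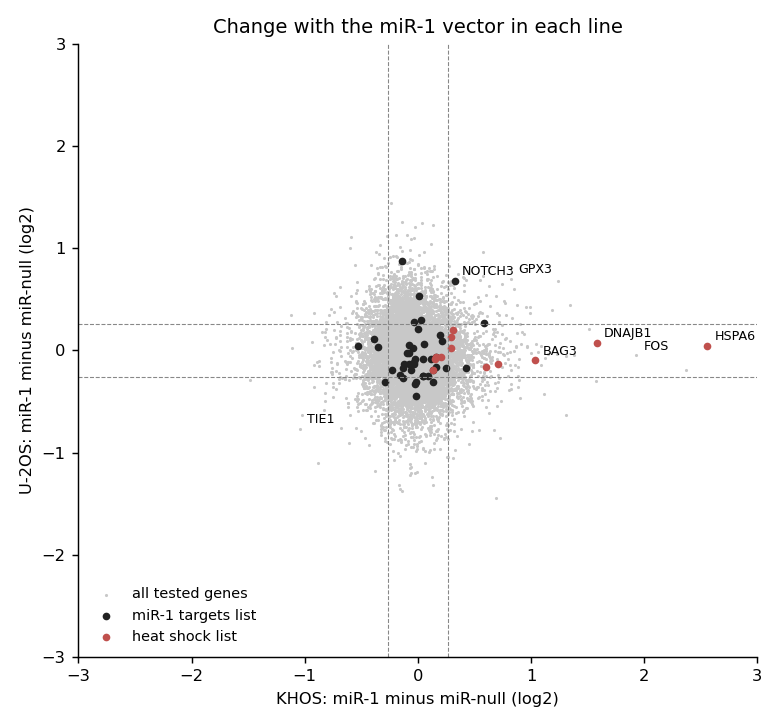
Change with the miR-1 vector against the miR-null vector (log2) in KHOS on the x axis and U-2OS on the y axis, 1 point per gene tested, with miR-1 targets in black, heat shock genes in red and dashed lines at 1.2-fold. The changes were not correlated across genes (r -0.062), and HSPA6 stood at 2.56 in KHOS and 0.05 in U-2OS.

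Among the fixed lists 3 passed at camera's preset correlation and 0 with an estimated one. Heat shock chaperones had a median of 0.22 with miR-1 and 11 of 12 fitted changes positive (adjusted p = 1.34e-05, p = 0.201 with an estimated correlation). This came from KHOS, where the median was 0.30, against -0.07 in U-2OS. HSPA6, a strictly inducible HSP70, had 2.56 in KHOS and 0.05 in U-2OS, DNAJB1, an HSP40 co-chaperone, 1.58 and 0.07, and BAG3, an HSP70 co-chaperone, 1.04 and -0.10. Immediate early genes had a median of 0.16 (adjusted p = 1.06e-04, p = 0.175 with an estimated correlation), 0.46 in KHOS and -0.02 in U-2OS. FOS, an AP-1 subunit, had 1.93 and -0.05, and ATF3, a stress-induced transcription factor, 0.78 and 0.35. G2/M genes had a median of -0.18 with 19 of 28 negative in both lines (adjusted p = 0.0199, p = 0.307 with an estimated correlation), led by the mitotic kinesin KIF11 at -0.49 and the topoisomerase TOP2A at -0.38. No member of these lists passed over all genes, and 0 passed when adjusted over the list alone. The heat shock call was lost without the KHOS miR-null array (0.02) or the KHOS miR-1 array (0.03), and the immediate early median was -0.14 without the KHOS miR-1 array, 0.26 without the KHOS miR-null array and 0.57 without the U-2OS miR-1 array. The G2/M call was lost without any of the KHOS miR-null (-0.08), KHOS miR-1 (-0.27), U-2OS miR-null (-0.15) and U-2OS miR-1 (-0.06) arrays.

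The other lists did not pass between miR-1 and miR-null. Interferon response genes had a median of -0.30 with 27 of 29 fitted changes negative (adjusted p = 0.188), -0.61 in KHOS and -0.10 in U-2OS, and the actin cytoskeleton list, which holds several known miR-1 targets, a median of -0.07 with 23 of 30 negative (adjusted p = 0.379). Pentose phosphate pathway genes had a median of -0.09 and muscle differentiation genes one of -0.10. In the endothelial list 1 of 6 genes, TIE1, was lower when adjusted over the list alone and 0 over all genes. Besides the miR-1 targets, camera's direction was up against a negative median for the osteoblast, collagen, DNA replication, G1, p53, NF-kB, EMT, microRNA machinery, HOX and TGF-beta lists. Of these, NF-kB, EMT and TGF-beta genes had a positive mean.

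The miR-null arrays were compared with the control arrays, to show what the empty vector and its transfection went with. No single gene passed in this contrast, but several stress-induced genes had higher values with the vector in both lines and all 28 G2/M genes lower ones. ATF3 had a fitted log2 change of 2.55 ± 0.28 (SE), DDIT3, the stress factor CHOP, 1.92 ± 0.18, and TSLP, an epithelial cytokine, 2.26 ± 0.19. COL5A2, a fibrillar collagen chain, had -1.51 ± 0.17 and SKP2, an F-box protein that drives entry into S phase, -1.08 ± 0.17. DNA replication genes were negative in both lines for 22 of 24.

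The other named genes had values of 2.60 for FOS, 2.17 for the histone demethylase KDM7A, 1.95 for HMOX1, the haem oxygenase, 1.86 for the GTPase GEM, 1.85 for CTH, a cystathionine lyase, 1.72 for PPP1R15A, the GADD34 phosphatase subunit, and 1.72 for HSPA6. On the negative side GALNT10, a mucin-type glycosyltransferase, had -1.43, the zinc transporter SLC39A10 -1.78, the receptor LGR4 -1.19, the Notch modifier LFNG -1.22, the pseudokinase TRIB2 -1.73, the osteoblast cadherin CDH11 -1.51, the myosin kinase MYLK -1.13 and the helicase HELLS -1.08. In limma the smallest adjusted p was 0.147 and 0 genes passed, with 1263 at an unadjusted p under 0.05, whereas the fit on the 4 arrays compared called 13 and a prior variance that follows the mean called 25. Without the KHOS control array 1346 genes passed and without the U-2OS control array 518. Across genes the changes in KHOS and U-2OS had a Pearson r of 0.256 and a Spearman rho of 0.247. By 1.2-fold 743 genes were higher and 1051 lower in both lines, 1794 together against 1141.3 expected, and 827 moved in opposite directions.

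DNA replication and G1/S genes had a median of -0.63 with 23 of 24 negative (adjusted p = 6.32e-13 in camera), and G2/M genes a median of -0.61 (adjusted p = 5.13e-19). Their p with an estimated correlation was 0.0375 and 0.0553, or 0.702 for both after adjustment. Over all genes 0 members of either list passed, and adjusted over the list alone 16 and 24 were lower. The replication helicase subunit MCM6 had -0.90, the kinesin KIF20A -1.21 and the cyclin CCNA2 -0.88. Oxidative phosphorylation genes (median -0.21, adjusted p = 0.0015) and actin cytoskeleton genes (-0.18, adjusted p = 0.0071) were lower as groups, with p = 0.104 and 0.122 with an estimated correlation. The ATP synthase subunit ATP5F1B had -0.46 and the tropomyosin TPM1 -0.77. Immediate early genes (0.55, adjusted p = 2.82e-07), NF-kB and cytokine genes (0.69, adjusted p = 4.91e-05) and unfolded protein response genes (0.32, adjusted p = 3.48e-06) were higher, with p = 0.127, 0.136 and 0.313 with an estimated correlation. Adjusted over the list alone 6, 3 and 4 of their members were higher, and 0 over all genes. PTGS2, the inducible cyclooxygenase, had 2.03, the chemokine CXCL8 1.44 and TRIB3, a pseudokinase of the amino acid stress response, 1.29. Interferon response genes had a median of 0.86 (adjusted p = 2.23e-07), with p = 0.352 with an estimated correlation. Without the KHOS control array the interferon median was -0.22 and the unfolded protein response median -0.01, and the oxidative phosphorylation (-0.27) and actin (-0.22) calls were lost. Without the KHOS miR-null array the interferon (0.15) and actin (-0.21) calls were lost. Lists near 0 differed in sign between median and mean for p53 (-0.05 and 0.02), heat shock (-0.06 and 0.08), hypoxia (-0.10 and 0.06) and telomere (0.01 and -0.03) genes.

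Array controls moved with the vector as well. Hybridization spike-ins, which are added to every sample before it goes onto the array, averaged 9.76, 10.13 and 9.93 (log2) on the KHOS control, miR-null and miR-1 arrays and 10.81, 11.33 and 11.65 on those of U-2OS. The 28S ribosomal RNA probe set read 13.68, 14.07 and 14.49 in KHOS and 13.79, 14.58 and 14.86 in U-2OS. Thus the arrays on which the stress genes were higher and the cell cycle genes lower also had the higher values of these controls. The interquartile range of an array was 3.07 in the U-2OS control and 2.84 and 2.75 in the U-2OS vector arrays, against 3.24, 3.32 and 3.36 in KHOS. The 3′ minus 5′ signal of the actin control probe sets was 2.68, 2.89 and 2.90 in KHOS and 2.40, 2.64 and 2.49 in U-2OS. For GAPDH it was 0.55, 0.59 and 0.53 in KHOS and 0.42, 0.48 and 0.46 in U-2OS.

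**Figure D2:**
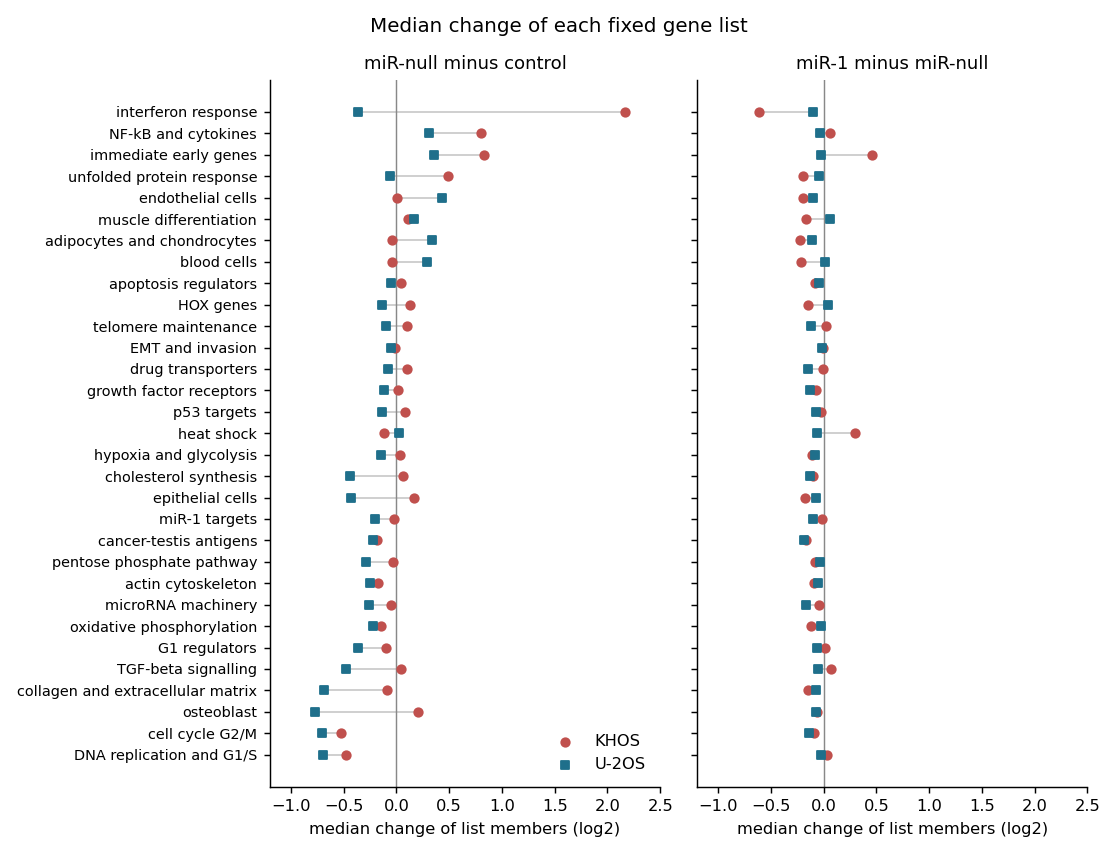
Median log2 change of each fixed gene list on the x axis, for miR-null minus control on the left and miR-1 minus miR-null on the right, with KHOS as red circles and U-2OS as blue squares. On the left, interferon response genes stood at 2.17 in KHOS and -0.36 in U-2OS, and cell cycle lists were negative in both lines.

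Because no gene separated miR-1 from miR-null, both kinds of vector array were set together against control, a comparison chosen after seeing the data. Here 62 genes passed, 46 higher and 16 lower with a vector, all with the same sign in both lines. The fit counts a line difference in the change as spread, so genes with opposite changes could hardly pass. The shared sign is therefore no result of its own. The larger share of rises depended on the settings. A prior variance that follows the mean gave 214 higher and 374 lower, the 75th percentile filter 157 and 229, and all probe sets 91 and 92. ATF3 rose by 2.83 ± 0.28 (log2, SE), or 7.10-fold, DDIT3 by 1.96 ± 0.14 and PPP1R15A by 1.84 ± 0.14, all genes of the integrated stress response. HMOX1 rose by 2.09 ± 0.21 and TSLP by 2.11 ± 0.17. COL5A2 fell by 1.42 ± 0.14 and SKP2 by 1.12 ± 0.12.

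Other genes of amino acid and oxidative stress that rose were CTH (1.85), TRIB3 (1.24), SESN2, a sestrin (1.55), CEBPB and CEBPG, a pair of C/EBP factors (1.16 and 1.27), and SLC7A11, the cystine transporter (1.11). The growth arrest genes GADD45A (1.63) and GADD45B (1.73), the phosphatase DUSP1 (1.54), KDM7A (2.23), GEM (2.00), ZNF165 (1.76) and CREBRF (1.75) rose too. The genes that fell included GALNT10 (-1.39), MYLK (-1.23), BRI3BP (-1.23), the protocadherin PCDH7 (-1.14), the kinetochore subunit SPC24 (-1.13), the ion channel TRPA1 (-1.11), LFNG (-1.09) and SYTL5 (-1.06). CEBPG, GADD45A, GADD45B, SESN2, DUSP1, TRIB3, CEBPB and SLC7A11 were chosen after their values were seen. The smallest adjusted p was 0.0133. The count was 0 without the KHOS miR-null, the KHOS miR-1 or the U-2OS miR-null array, 21 without the U-2OS miR-1 array, 520 without the U-2OS control (446 higher and 74 lower) and 1931 without the KHOS control (418 and 1513). Spike-ins were higher by 0.48 and 28S ribosomal RNA by 0.77 on average in the vector arrays than in the control array of their line.

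**Figure D3:**
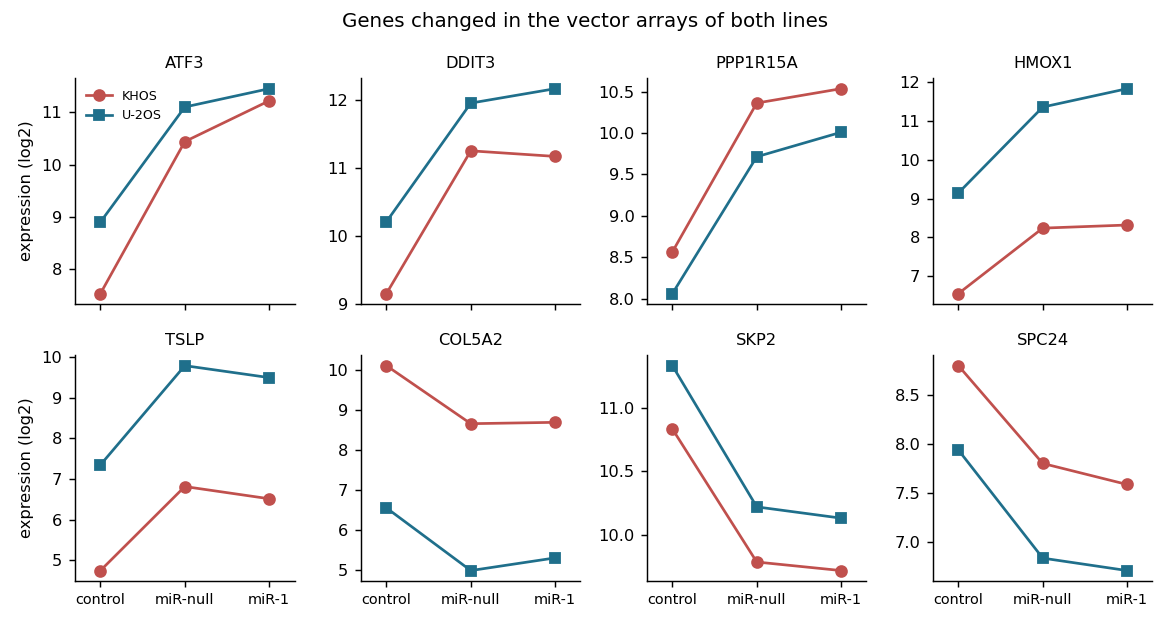
Expression (log2, y axis) of 8 genes on the control, miR-null and miR-1 arrays (x axis) of KHOS, red circles, and U-2OS, blue squares, with 1 array per point and a separate y scale per gene. Both vector arrays lay above the control array for ATF3, DDIT3, PPP1R15A, HMOX1 and TSLP and below it for COL5A2, SKP2 and SPC24.

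In this comparison all 28 G2/M genes were lower when adjusted over the list alone and 0 over all genes, with a median of -0.65 (adjusted p = 7.04e-18 in camera). Of 24 DNA replication genes 19 were lower when adjusted over the list alone and 0 over all genes, with a median of -0.65 (adjusted p = 9.54e-12). Their p with an estimated correlation was 0.045 and 0.0146, which adjusted to 0.633 and 0.453. In fry their adjusted p was 0.0539 and 0.0128, and DNA replication genes were the only list to pass. Of 19 immediate early genes, ATF3 and DUSP1 rose over all genes, and 11 rose and 2 fell when adjusted over the list alone (median 0.71, adjusted p = 5.23e-08). Of 21 unfolded protein response genes 4 rose over all genes, DDIT3, PPP1R15A, SESN2 and TRIB3, and 6 when adjusted over the list alone (median 0.30, adjusted p = 1.01e-04). These are stress-induced genes of the ATF4 branch. NF-kB and cytokine genes had a median of 0.69 (adjusted p = 1.48e-05), with 7 higher when adjusted over the list alone and 0 over all genes. With an estimated correlation the p was 0.0753, 0.292 and 0.0816 for these lists. Oxidative phosphorylation (-0.24, adjusted p = 3.70e-04), actin cytoskeleton (-0.23, adjusted p = 0.0014) and cancer-testis (-0.25, adjusted p = 0.0294) genes were lower, with p = 0.118, 0.158 and 0.237 with an estimated correlation. Interferon genes had a median of 0.66 (adjusted p = 7.09e-06), with p = 0.364 with an estimated correlation, and without the KHOS control array their median was -0.48 and that of the unfolded protein response -0.08, and the oxidative phosphorylation (-0.28), actin (-0.24) and cancer-testis (-0.33) calls were lost. The cancer-testis call was also lost with no level filter (adjusted p = 0.163), at the 75th percentile filter (0.162), with a prior variance that follows the mean (0.0603), without the KHOS miR-1 array (-0.23) and without the U-2OS control array (-0.25). Of 25 collagen and matrix genes COL5A2 fell over all genes and 6 fell when adjusted over the list alone. Median and mean differed in sign for the p53, heat shock, hypoxia, EMT, and adipocyte and chondrocyte lists.

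The lines were then compared in their change with a vector, also chosen after seeing the data. Interferon response genes were higher with a vector in KHOS and not in U-2OS. IFIH1, the RNA sensor MDA5, changed by 2.78 in KHOS and -1.74 in U-2OS, a difference of 4.52 ± 0.31 (SE), and RSAD2, the antiviral enzyme viperin, by 3.98 and 0.19. U-2OS instead gained MMP1, an interstitial collagenase, by 5.25 against -0.22 in KHOS, a difference of -5.47 ± 0.25. It also gained PRR9 by 5.03 against -0.11 and IL1A, the interleukin 1 alpha gene, by 2.38 against -0.18.

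The difference passed for 296 genes, 259 with the higher change in KHOS and 37 with the lower, and the median over all genes was 0.14. After a further quantile normalization, which moved that median to -0.05, 19 genes passed, 13 higher and 6 lower. Of 29 interferon genes 19 passed over all genes and 28 when adjusted over the list alone, all higher in KHOS, with a median difference of 2.52 (adjusted p = 4.47e-24 in camera). With an estimated correlation the p was 0.113. In the miR-null arrays alone the list stood at 2.17 in KHOS, with 29 of 29 genes positive, and at -0.36 in U-2OS. Large differences also included TRIM22 (4.85), IFI27 (3.81), DDX60L (3.58), GBP1 (3.36), RTP4 (3.17) and SAMD9 (3.09), all interferon-induced, and DHRS2, a reductase (3.21). RUNX2, the osteoblast transcription factor, changed by 0.86 in KHOS and -2.27 in U-2OS. On the other side were LINC01516 (-3.21), LINC00520 (-2.22), the bone matrix protein SPP1 (-2.04), the kinase PAK6 (-1.13 in KHOS and 0.86 in U-2OS), BCL2A1, an apoptosis inhibitor (-1.86), the stromelysin MMP3 (-1.63) and LINC03002 (-1.59). RSAD2 and RTP4 in U-2OS and PRR9, IL1A, LINC01516, MMP3 and LINC03002 in KHOS stayed under the level filter of 5.11 on all 3 arrays of that line, near background, where a change may not be read. The count for the difference was 7 without the KHOS miR-1 array, 6 without the KHOS miR-null array, 440 without the U-2OS miR-1 array and 1531 without the U-2OS miR-null array, and each line had only 1 control array, whose own error enters every call.

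**Figure D4:**
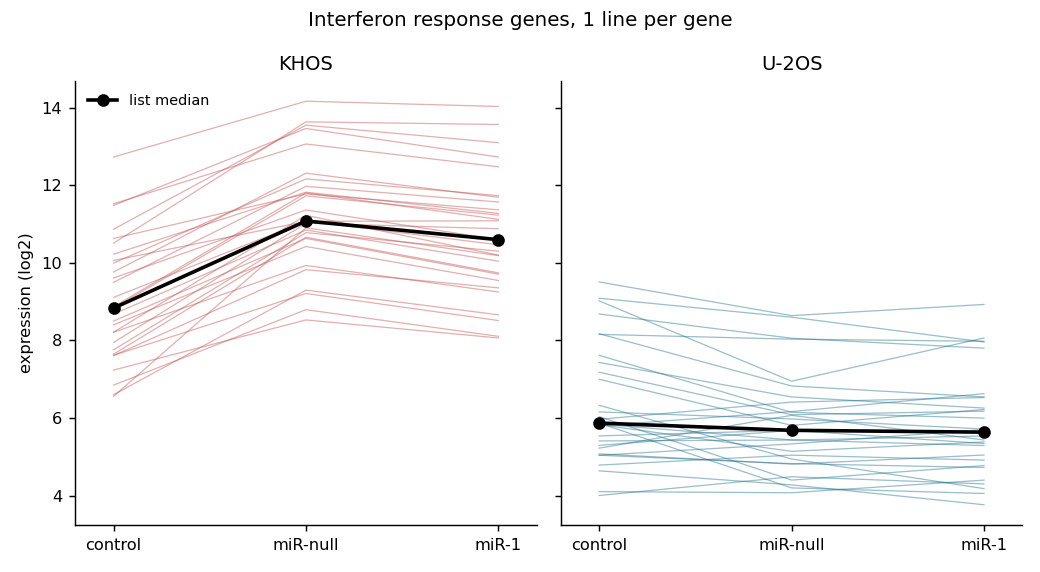
Expression (log2, y axis) of the 29 measured interferon response genes, 1 thin line per gene, on the control, miR-null and miR-1 arrays (x axis) of KHOS (left) and U-2OS (right), with the list median in black. In KHOS 29 of 29 genes were higher on the miR-null than on the control array.

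No gene differed between the lines in the miR-1 change, here the miR-1 array of a line against its miR-null and control arrays together, so the change with a vector enters this contrast. Of the lists only heat shock genes passed at the preset correlation, with a median of 0.26 and all 12 members positive (adjusted p = 0.0406 in camera), and the call was lost with an estimated correlation (p = 0.109), at the 75th percentile filter (adjusted p = 0.0981), without the KHOS miR-null array (0.24, adjusted p = 0.103) and without the U-2OS miR-null array (0.35, adjusted p = 0.143). Over all genes 0 members passed and adjusted over the list alone 0. In limma the smallest adjusted p was 0.9997 and 276 genes had an unadjusted p under 0.05. Simulated 4-fold differences were recovered in 0% of cases, so a difference of that size was not detectable gene by gene.

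KHOS and U-2OS differed in 7103 of 12958 genes over the 3 treatments, 3928 higher in KHOS and 3175 higher in U-2OS. The SDs given here run over the 3 treatments of a line, so they hold treatment differences as well as array error. KHOS expressed GREM1, a BMP antagonist, at 12.31 ± 0.20 (log2, SD) against 3.62 ± 0.16 in U-2OS. DKK1, a Wnt inhibitor, stood at 12.48 ± 0.24 against 4.02 ± 0.06. U-2OS expressed MAGEA4, a cancer-testis antigen, at 12.78 ± 0.24 against 3.94 ± 0.13, and MMP3 at 13.35 ± 1.09 against 4.67 ± 0.20. IFIT1, an interferon-induced antiviral protein, differed by 5.44 on the control arrays.

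Fitted differences were 8.69 ± 0.17 (SE) for GREM1 and -8.85 ± 0.15 for MAGEA4, each with adjusted p = 1.77e-06. KHOS was also higher in the tight junction protein CLDN11 (8.10), the ectonucleotidase NT5E (8.05), the proteoglycan SRGN (7.89), IFIT1 (7.48), the transcription factor KLF4 (7.42), NETO2 (7.24), the ubiquitin hydrolase UCHL1 (7.24) and the cytochrome CYP1B1 (7.15). U-2OS was higher in MAGEA6 (-8.78), MMP3 (-8.68), MAGEA12 (-8.33), MAGEA1 (-7.93), the cyclin CCND2 (-7.80), SUN3 (-7.60), the small heat shock protein CRYAB (-7.42), DHRS2 (-7.40) and MAGEB2 (-7.13). For all of these genes but UCHL1, CRYAB and DHRS2 the mean of the lower line lay under the level filter of 5.11, near background, so the size and order of these fitted differences depend on the floor of the arrays. The probe sets of MAGEA6, MAGEA12 and MAGEA1 end in x_at, and signal may be shared among these near-identical genes. Differences of at least 2-fold were found in 3196 genes and of at least 16-fold in 222. The exact Mann-Whitney test of 3 against 3 arrays called 0, since it cannot go below p = 0.1, though 8064 genes were fully separated by at least 1.2-fold, where chance separates 10%. A further quantile normalization moved the median of all genes from 0.00 to -0.17 and the split to 3094 higher and 4213 lower, and median centring moved them to 0.12 and to 4360 and 2306. The count was 4471 without either miR-null array.

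**Figure D5:**
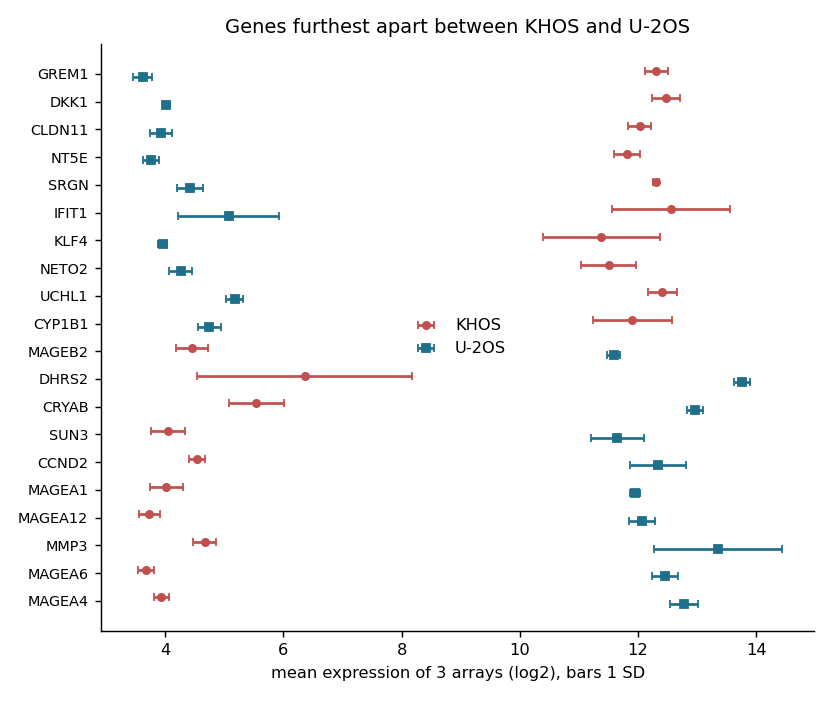
Mean expression (log2, x axis) over the 3 arrays of KHOS, red circles, and of U-2OS, blue squares, with bars of 1 SD, for the 10 genes furthest above and the 10 furthest below in KHOS. The 3 arrays of a line are its 3 treatments, so the bars hold treatment differences too. GREM1 stood at 12.31 in KHOS and 3.62 in U-2OS, and MAGEA4 at 3.94 and 12.78.

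Between the lines 4 lists passed in camera. Of 20 cancer-testis antigens listed 7 reached the level filter, and all 7 were lower in KHOS, with a median of -7.93 (adjusted p = 5.08e-07), or -0.87 with no level filter. Of the interferon genes 27 of 29 were higher, 28 when adjusted over the list alone, with a median of 4.34 (adjusted p = 3.14e-09). This averages the conditions: the median was 2.61 on the control arrays, 5.52 on the miR-null arrays and 4.76 on the miR-1 arrays. IFIT2, IFI44L and IFIT3 differed by 7.03, 7.02 and 6.55 in the fit and by 5.21, 5.12 and 4.71 on the control arrays. Of 28 G2/M genes 16 were higher and 2 lower, with a median of 0.59 (adjusted p = 0.0243), or 0.39 on the control arrays, among them the proliferation marker MKI67 (1.95) and the kinase AURKB (1.64). Of 12 heat shock genes 10 were lower, with a median of -0.72 (adjusted p = 0.0019), among them CRYAB, HSPB1 (-2.39), HSPA6 (-2.25) and DNAJB1 (-2.11). With an estimated correlation the p was 0.0306, 0.299, 0.325 and 0.299 in that order, and none passed after adjustment, the smallest adjusted p being 0.948. In fry the adjusted p was 6.45e-04, 0.0868, 0.0562 and 0.0562 in that order, so only cancer-testis antigens passed in both tests. Fry also passed hypoxia and glycolysis (0.0049), EMT and invasion (0.0049) and growth factor receptor (0.0069) genes, which camera did not. The G2/M call was also lost with all probe sets (adjusted p = 0.0764), at the 75th percentile filter (0.196), without the treatment term (0.206), without either control array (0.68, adjusted p = 0.0567) and without either miR-null array (0.59, adjusted p = 0.0557). Spike-ins were lower in KHOS than in U-2OS for each treatment, at 9.76 against 10.81 on the control arrays.

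The remaining lists held genes of both signs. Unless stated otherwise, the counts over all genes and adjusted over the list alone were the same. Invasion and mesenchymal genes had 13 higher and 6 lower of 24, with TWIST1 at 6.46, the urokinase PLAU at 4.69 and ZEB2 at 4.06. Of 9 osteoblast genes 4 were higher and 5 lower, with CDH11 at 5.65, RUNX2 at 4.32 and BMP2 at -2.83. Collagen and matrix genes had 10 higher and 5 lower of 25, with COL5A2 at 3.55 and COL12A1 at -3.00, and TGF-beta genes 8 higher and 5 lower of 22, with SMAD4 at 1.89. Of 42 miR-1 targets 14 were higher and 4 lower, among them HDAC4 (4.05), the potassium channel KCNJ2 (3.90) and PAX3 (3.77). Growth factor receptors had 7 higher and 5 lower of 17, or 6 lower when adjusted over the list alone, with PDGFRA at 3.31 and EGFR at 2.88. Immediate early genes had 9 higher and 3 lower of 19, with the ERK phosphatase DUSP6 at 6.66, and NF-kB genes 9 higher and 3 lower of 18, with the cytokine IL11 at 3.07 and IL1A at -2.97. HOX genes had 8 higher and 7 lower of 22, or 9 higher when adjusted over the list alone, with HOXD10 at -4.28. Drug transporters had 4 higher and 4 lower of 14, with the efflux pump ABCB1 at -3.97 and the cholesterol exporter ABCA1 at 2.68.

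Cell cycle regulators of G1 had 5 higher and 6 lower of 14, or 6 higher when adjusted over the list alone, with MYC at -2.20 and RB1 at 1.76, and DNA replication genes 8 higher and 4 lower of 24, with CCNE2 at 3.68. Of 22 p53 targets 4 were higher and 8 lower, or 5 and 9 when adjusted over the list alone, with TP53INP1 at 2.32 and GDF15 at -2.01. Apoptosis regulators had 8 higher and 4 lower of 19, or 9 higher when adjusted over the list alone, with HRK at -4.17 and APAF1 at 2.63. Hypoxia and glycolysis genes had 6 higher and 11 lower of 27, with the enolase ENO2 at -3.19, and pentose phosphate genes 6 higher and 1 lower of 10, with PGLS at 1.77. Oxidative phosphorylation had 8 higher and 0 lower of 26, cholesterol synthesis 4 higher and 1 lower of 17, and the unfolded protein response 8 higher and 7 lower of 21. MicroRNA machinery had 5 higher and 3 lower of 15, with DICER1 at 1.73 and AGO1 at -1.57. Telomere maintenance had 3 higher and 2 lower of 10, with the shelterin TERF1 at 1.15 and ATRX at -0.74. Actin cytoskeleton genes had 6 higher and 6 lower of 30, or 5 lower when adjusted over the list alone, with TAGLN at -2.73, and muscle differentiation genes 2 higher and 4 lower of 9, with MEF2C at 3.37. Of markers of other cell types, 2 of 9 epithelial genes were higher and 3 lower (EPCAM 2.89, KRT8 -3.11), 1 of 6 blood genes higher and 1 lower (LAPTM5 2.25), 2 of 6 endothelial genes higher and 2 lower (ROBO4 3.90), and 1 of 5 adipocyte and chondrocyte genes higher (SOX9 0.86), or 0 when adjusted over the list alone. Median and mean differed in sign for the muscle, osteoblast, apoptosis, unfolded protein response, cholesterol, HOX, growth factor receptor, blood and endothelial lists.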

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

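The tests of array scaling, of KHOS RNA behind the interferon genes, of the vector response and of the single miR-1 pool were chosen after the results were seen; the others were written down before the value they measure was known.

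The change with a vector differed between KHOS and U-2OS for 296 genes, and interferon response genes led it with a median difference of 2.52. After quantile normalization the list's median less that of all genes was 2.54 (2.38 before), above the upper limit of matched random lists (0.25). Those lists held independently drawn genes, so the limit is narrow for this list, whose estimated correlation was 0.64. That the median kept its size argues against array scaling as the whole cause, although the list's genes that passed one by one fell from 19 to 4. If the U-2OS control array had held KHOS RNA, 18 interferon genes would have needed a median share of 4.99%, but 26 genes high in KHOS and at the floor in the U-2OS vector arrays put the share at -0.0095% (quartiles -0.117% to 0.142%). A response to the vector that differs between the lines, such as DNA sensing, may underlie the pattern, but with 1 control pool per line it cannot be told apart from the handling of those pools, and the list's p with an estimated correlation was 0.113.

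Outside the interferon list 277 genes had a line difference, with a median size of 1.57 and a median SE of 0.25. After quantile normalization the median size less that of all genes was 1.49 with an SE of 0.24. These genes were chosen for their difference on the same arrays, so this value does not decide on scaling. Only 11 of them still passed in this fit, which kept the genes chosen before the normalization (choosing them again gave 19 genes in all, 18 of them among the 296). All 277 kept their sign relative to the median of all genes. The prior degrees of freedom, which limma draws from the spread of all genes, fell from 6.35 to 4.06, and fewer of them raise each p. Whether this gave the loss was not tested. KHOS RNA in the U-2OS control array would have had to reach 35.4% over the 118 genes that it could explain, against the share of -0.0095% above. Whether array scaling, the vector, the lines or a single control pool gave these differences stays open and was not tested further.

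Heat shock genes had a line difference in their miR-1 change with a median of 0.26, a call at the preset correlation (adjusted p = 0.0406) that was lost with an estimated one (p = 0.109). The test of scaling used their change from miR-null to miR-1 in KHOS, not the line difference above. For that change their median less that of all genes was 0.34 after quantile normalization and 0.34 before. The value after normalization lay above the upper limit of random lists of independently drawn genes (0.09), which argues against scaling as the cause of the KHOS change. A signal ceiling in U-2OS could not be judged, because only 1 of 12 members lay below its KHOS miR-1 level in U-2OS, where 11 lay above it and the highest reached 14.54. Handling of the single KHOS miR-1 pool cannot be told apart from an effect of miR-1.

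For the line difference in the vector change 5 other lists passed at the preset correlation, and none with an estimated one (p = 0.0952 for p53 targets, 0.164 for NF-kB, 0.409 for the unfolded protein response, 0.0719 for TGF-beta and 0.228 for endothelial genes). The median was 0.61 for p53 targets, with the death receptor FAS at 1.58, 0.90 for NF-kB and cytokine genes, 0.46 for the unfolded protein response, with XBP1 at 1.15, and 0.57 for TGF-beta signalling, with INHBA at 2.37 and FST at 1.43. Endothelial genes had a median of -0.49, with PECAM1 at -1.21. Over all genes 1, 5, 1 and 2 members of the first 4 lists passed as higher, and adjusted over the list alone 6, 11, 2 and 7. Of NF-kB genes 1 was lower over all genes and 2 when adjusted over the list alone, and of endothelial genes 1 and 1. The p53 call was also lost at the 75th percentile filter (adjusted p = 0.0655) and with median centring (0.0508), NF-kB with median centring (0.0631), the unfolded protein response with all probe sets (0.059) and at the 75th percentile filter (0.147), and endothelial genes after quantile normalization (0.0726) and at the 75th percentile filter (0.916). Without the U-2OS miR-null array the p53 (0.60), NF-kB (0.89), unfolded protein response (0.43) and endothelial (-0.34) calls were lost, without the KHOS miR-1 array p53 (0.52), NF-kB (0.88) and endothelial (-0.29), and without the KHOS miR-null array the unfolded protein response (0.31). Control probe sets, which no comparison used, also stood above the control arrays, the hybridization spike-ins by 0.48 on average and 28S ribosomal RNA by 0.77 in the vector arrays.

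The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The split by line was the 1 that reached 7103 genes, and the highest of the others gave 0. Those others mix the lines and were fitted without a line term, so the line difference counted as spread in them. Their 0 was thus nearly fixed in advance, and no conclusion is drawn from it.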

How the results depend on the processing

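The comparison of vector arrays with control, the line difference in it and all their alternatives were chosen after seeing the data, as were the alternatives for changes shared by both lines and the leave-one-out counts and values of lists other than the miR-1 targets. Of 9439 results for single genes and lists under an alternative, 8795 kept their side of the threshold, 264 no longer passed, 374 newly passed and 6 reversed. Direction was checked only for results that had passed in the main fit. The cause was not tested except where stated. The count for miR-1 against miR-null was 0 under every alternative run. With 1 array per line and treatment, leaving an array out assumes that the remaining arrays vary alike; the line difference in the vector change has no value without a control array, nor that in the miR-1 change without a miR-1 array. Seed-site comparisons were not run. The line term pairs the treatments within each line, and without it miR-1 against miR-null had 0 genes and 2 lists. Arrays carry no measure of signal over background here, so low-level genes were limited only by the level filter.

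With all probe sets, vector against control gave 183 genes and miR-1 against miR-null 6 lists. With no level filter these were 103 genes, and lists numbered 9 between the lines, 5 for the line difference in the miR-1 change and 11 for that in the vector change. At the 75th percentile filter, where fewer genes are tested, 4713 genes differed between the lines, 386 with a vector and 553 in the line difference of the vector change, 0 lists in that of the miR-1 change, 161 genes moved together with miR-1, and the endothelial list's line difference turned to 0.0826. Repeated quantile normalization gave 98 genes with a vector, 19 for its line difference, and 5 and 4 lists for miR-1 and its line difference. Median centring gave 40 genes with a vector. The trended prior gave 25 genes for miR-null against control, 588 with a vector and 863 for its line difference. The 4 arrays compared alone gave 13 genes for miR-null against control. For miR-1, control arrays in place of miR-null gave 9 lists, and both together 8. An estimated correlation left 0 lists in each of the 6 comparisons, where the few residual degrees of freedom make passing nearly impossible. For cancer-testis antigens between the lines the estimated correlation was 0.0063, below the preset 0.01. Their unadjusted p in camera still rose from 3.28e-08 to 0.0306. The exact Mann-Whitney test left 0 genes between the lines, as its smallest p allows none.

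Leaving out 1 array gave 0 to 1346 genes for miR-null against control, 4471 to 8765 between the lines, 0 to 1931 with a vector and 6 to 1531 for its line difference. Lists numbered 1 to 5 for miR-1, 2 to 7 for its line difference and 2 to 7 for that of the vector. Without the KHOS control array the interferon median was -0.22 for miR-null and -0.48 for the vectors, and the unfolded protein response -0.0136 and -0.0802; the vector contrast then rests on U-2OS alone by construction. Without the U-2OS control array these were 1.94 and 1.77, and 0.450 and 0.447. Without the KHOS miR-1 array the immediate early median for miR-1 was -0.14, and without the U-2OS miR-1 array 0.565.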

Other observations

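All genes below were chosen after their values were seen, and no further hypothesis was tested.

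The interferon pattern in KHOS included an interferon gene and an RNA sensor. IFNB1, the interferon beta gene, changed with a vector by 2.38 in KHOS and 0.39 in U-2OS, a line difference of 1.99 (adjusted p = 0.0365 in limma). The U-2OS arrays read IFNB1 near background, under the level filter of 5.11. RIGI, a cytosolic RNA sensor, differed by 2.69, OASL, an oligoadenylate synthetase-like protein, by 3.03, and PSMB9, an immunoproteasome subunit, by 2.73. Genes of other functions differed as well, with GATA6, a lineage transcription factor, at 2.98 and PDGFC, a growth factor, at 2.78, of which 0.13 came from KHOS and -2.66 from U-2OS.

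Among the genes that rose with a vector in both lines were DUSP10, a phosphatase of stress kinases (adjusted p = 0.0138), MXD1, a MYC antagonist (1.71 ± 0.15, SE), DDIT4, an inhibitor of mTORC1 (1.33 ± 0.15), GABARAPL1, an autophagy protein (1.32 ± 0.15), IRS2, an insulin receptor substrate (1.31 ± 0.16), and BTG1, an antiproliferative factor (1.05 ± 0.14). SCD5, a fatty acid desaturase, fell by 0.96 ± 0.13 and FHOD1, a formin, by 0.90 ± 0.13. Each passed in limma with an adjusted p between 0.0138 and 0.0464.

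A further 4297 probe sets reached the level filter but carried no gene symbol or several. Of these, 0 passed between miR-1 and miR-null (49 at an unadjusted p under 0.05), 1 between miR-null and control and 9 between vector and control. For the line difference in the vector change 21 passed, and between the lines 1902, 1008 of them higher in KHOS.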
